A study of Danio rerio with 12 samples.

How the data were processed

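Whole-body zebrafish RNA from 12 libraries (4 groups of 3: Control, BaP, diclofenac and their mixture, 48 h) was sequenced as 150 bp paired reads, 40000000 to 80000000 per library, per the labels' protocols. Samples were assigned to groups from their labels. The series was analysed from the authors' own comparison table, in which replicates are already combined; values per library were not analysed here. The submitters' processing notes name kallisto, edgeR, limma and the build GRCz11, without versions or roles; filters and library scaling are not given in the sources used here.

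The deposited log2 fold changes compare each treatment with Control, per the file headers. Their log base is not stated; it was taken as 2 because 2 to the power of the deposited average log2 CPM summed to 1.01e+06, close to the total that CPM values have. The average is described as that of a single treatment, but its 3 deposited columns were identical in every entry, so it is an average over the whole fit. The deposited likelihood ratio is a score with no fixed range, per the file headers. The deposited p-value equalled the chi-square tail of that ratio on 1 degree of freedom to within a relative difference of 9.86e-13, so it is not adjusted for multiple testing. The authors' column descriptions give a limit of 1.5 on the log fold change. Entries are gene identifier by transcript class, 35497 in all for 30628 gene identifiers, of which 2443 lie at the floor of the average.

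The tests fixed before the data were examined assumed values per library: count models or limma on log values, with other normalizations and tools, pseudocounts, other samples in the fit, each replicate left out, a replicate block, estimated inter-gene correlations, rotation tests and other splits of the samples. None of these could be run on a comparison table. In their place the deposited p-values were adjusted by the Benjamini-Hochberg method over the 21622 entries with an average of at least 1 CPM, two-sided, at a threshold of 0.05. All p-values rest on the authors' model of the spread between 3 libraries per group.

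Differences between treatments were tested approximately. The variance of a log2 fold change was implied as its square divided by the likelihood ratio. The largest of the 3 implied variances of an entry was used, a choice made after seeing the data, because the median gave degenerate values for entries absent from some groups. The median ratio of largest to smallest was 1.03. The 3 fold changes appear to come from a single fit, so this ratio does not show that the groups had equal spread. Equal spread was assumed for all differences between treatments and could not be tested. With equal group sizes and equal spread, a difference between treatments has that variance and the interaction (mixture minus BaP minus diclofenac, each against Control) double it. A Wald test against the chi-square distribution on 1 degree of freedom followed, adjusted as above.

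The tests were tested on simulated data with 4000 genes, 3 libraries per group of 20000000 reads and 200 changed genes of each kind. For the mixture against BaP the approximate test recovered 15%, 62%, 89% and 99% of changes of 0.5, 1, 2 and 4 log2 units, and 7.34% of its calls were false. For the mixture against diclofenac it recovered 22%, 63%, 94% and 99%, with 2.80% false, and for the interaction 4%, 26%, 68% and 94%, with 4.95% false. The simulated tests used the true spread. These rates hold for that share of changed genes, and recovery is lower where fewer genes change.

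Gene lists, 33 in all, were fixed before the data were examined. Of 1326 members 1273 were matched by symbol, 20 of them through older names in a RefSeq table (assembly GRCz12tu, used for names only). Each was tested with limma's camera on the signed root of the likelihood ratio, 1 entry per symbol (the most abundant), with a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Lists with under 5 measured members were not tested. Because no correlation can be estimated without values per library, presets of 0.05 and 0.1 were added after seeing the data. The other alternatives added then were a median-centred fold change, 1 entry per symbol, Benjamini-Yekutieli adjustment, the 1.5 limit, the median variance, ranks, and protein-coding entries alone. The alternatives fixed in advance that could be run were no abundance filter, at least 5 CPM, and at least 2-fold.

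Named genes followed a rule fixed before the data were examined: up to 8 higher and 8 lower genes by p per comparison, up to 3 members per called list, 12 genes named in advance (1 of them is not reported here), and up to 5 called members of any list. Its condition that all libraries of a group lie on one side of the other group could not be applied, and its limit of 30 genes was exceeded in the tables so that each called list kept its examples. The shared-control simulation drew unchanged groups 100 times from the implied variances. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3 with limma 3.58.1.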

Results

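RNA from whole zebrafish was sequenced after 48 h with benzo[a]pyrene (BaP, a polycyclic aromatic hydrocarbon that activates the Ah receptor), with diclofenac (a non-steroidal anti-inflammatory drug that inhibits cyclooxygenases), with the mixture of both, or with neither (Control). Each of the 4 groups had 3 libraries, 12 in all, described in the labels as independent replicates. The authors' deposited table gives, for each of 35497 entries, a log2 fold change of each treatment against Control with a likelihood ratio and a p-value. An entry is one transcript class of one gene identifier, so a gene can have several. Values per library were not analysed here, so the depth of each sample is unknown from the table, and no mean or SD per group is given. The labels state 40000000 to 80000000 reads of 150 bp per library. Errors below are standard errors (SE) or 95% intervals implied by the authors' fold change and likelihood ratio. Calls are at a Benjamini-Hochberg adjusted p under 0.05 over the 21622 entries averaging at least 1 CPM (reads scaled to a common library total).

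The first comparison asked what BaP alone changed. Genes of the Ah receptor response rose, and few other entries passed the test. The cytochrome P450 gene cyp1a (ENSDARG00000098315), which oxidises BaP and is the classical Ah receptor target, rose by 6.80 on the log2 scale in the authors' deposited table, with a 95% interval of 6.18 to 7.42 (adjusted p = 3.68e-99, likelihood ratio test). The related P450 genes cyp1c1 and cyp1c2 rose by 2.93 and 2.27 in the authors' deposited table. For cyp1b1 the protein-coding entry rose by 3.92 and the more abundant entry, of the nonsense-mediated decay class, by 3.61 in the authors' deposited table; the second entry stands for the gene below. The Ah receptor repressor gene ahrra rose by 2.89 and the forkhead transcription factor gene foxq1a by 2.25 in the authors' deposited table. The second repressor gene ahrrb, also named in advance, averaged under 1 CPM and was not tested.

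Of 17 measured members of the Ah receptor target list, 8 rose and 0 fell over all entries tested, and 13 rose when adjusted over the list alone. The list's median log2 change was 1.51 (camera, adjusted p = 3.24e-139), and the call held at an inter-gene correlation of 0.1 (adjusted p = 6.19e-63). Outside that list, nfe2l2b, a relative of the antioxidant regulator Nrf2, rose by 1.92 in the authors' deposited table. The pituitary hormone gene prl (prolactin) and the otolith matrix gene stm (starmaker) fell, with log2 changes of -1.36 and -0.79 in the authors' deposited table. Erythrocyte and heme genes had a median of 0.43, with 0 of 30 called over all entries, 4 higher when adjusted over the list alone, and a list call that held at a correlation of 0.1 (camera, adjusted p = 5.32e-14, and 9.21e-05 at 0.1). Skeletal muscle genes had a median of 0.23 and liver genes of -0.21, with 0 called in either list over all entries and both list calls kept at 0.1 (camera, adjusted p = 1.91e-09 and 7.77e-08, and 0.0243 for each at 0.1). The muscle quartiles were 0.16 and 0.27, a narrow spread beside the implied SE of 0.17 for ryr3, the member with the smallest p. The correlation among members could not be estimated, so these list calls rest on the presets. Among the 34 measured members of the DNA damage response list, 0 were called (median log2 change -0.01, camera adjusted p = 0.674). The cell cycle inhibitor gene cdkn1a, a member of that list, had a log2 change of 0.53 in the authors' deposited table and did not pass (adjusted p = 1), nor did mdm2, another member, at -0.01 (adjusted p = 1).

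BaP changed 32 entries in total, 25 higher and 7 lower. At an unadjusted p under 0.05 there were 860 entries, against 1081 that uniform p-values would give. The deposited p-values thus appear conservative for BaP, and this count does not show that nothing beyond the 32 changed. Several of the 32 were entries near the abundance floor with very large fold changes, such as rpe at -7.72 in the authors' deposited table.

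**Figure D1:**
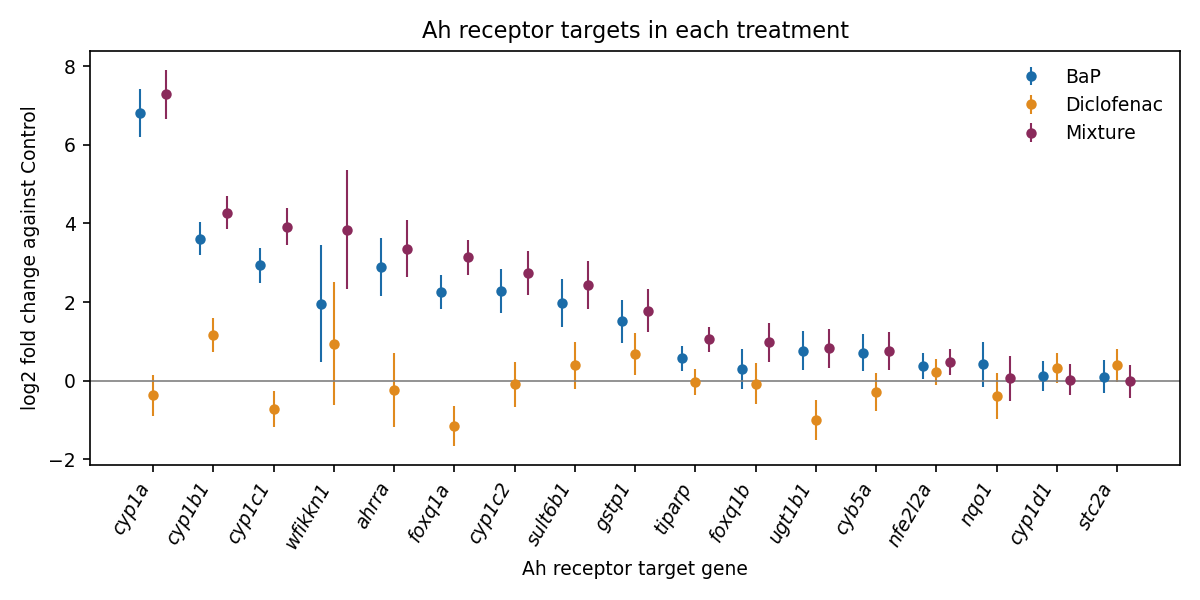
Log2 fold change against Control of the 17 Ah receptor targets measured, 1 entry per gene, after BaP, diclofenac or the mixture; points are the authors' values and bars the implied 95% intervals. The point for cyp1a lies at 6.80 with BaP, at -0.38 with diclofenac and at 7.28 with the mixture.

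The second comparison asked what diclofenac alone changed. It raised stress, inflammation and sterol synthesis genes and lowered skeletal muscle, cartilage and mitochondrially encoded genes. The AP-1 transcription factor genes fosl1a, atf3 and junbb rose by 5.50, 4.26 and 3.38 in the authors' deposited table (adjusted p = 1.46e-135, 4.05e-61 and 2.04e-46, likelihood ratio test). The small heat shock protein gene hspb11 rose by 5.40 and the co-chaperone gene bag3 by 2.67 in the authors' deposited table. The muscle genes ampd1 (AMP deaminase), tnni2b.2 (fast troponin I) and atp2a1l (a calcium pump) fell, with log2 changes of -6.11, -3.70 and -2.63 in the authors' deposited table. Other muscle genes, tcap and mustn1b, which are outside the muscle list, rose by 5.29 and 3.57 in the authors' deposited table.

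Of 69 measured skeletal muscle genes, 47 fell and 4 rose (median -0.75, camera adjusted p = 1.05e-24), and adjusted over the list alone 48 fell and 6 rose. Of 50 heat shock and unfolded protein response genes, 25 rose and 8 fell (median 0.53, camera adjusted p = 1.49e-21); adjusted over the list alone the counts were 29 and 9. Of 46 inflammation and innate immunity genes, 20 rose and 2 fell (median 0.66, camera adjusted p = 6.13e-12), or 23 and 3 adjusted over the list alone, among them the complement genes c6 and c4b and the cytokine signalling suppressor socs3b, at 2.78, 3.32 and 2.41 in the authors' deposited table. Leukocyte markers rose in 7 of 17 cases and fell in 0 (median 0.57, camera adjusted p = 0.00182, and 0.0818 at an inter-gene correlation of 0.1), or 9 and 1 adjusted over the list alone. Of 26 cholesterol synthesis genes, 14 rose and 0 fell (median 0.66, camera adjusted p = 2.87e-07), or 15 and 0 adjusted over the list alone. Their regulator insig1 and the sterol demethylase gene cyp51 rose by 1.64 and 0.89 in the authors' deposited table. Of 38 cartilage, bone and collagen genes, 18 fell and 1 rose (median -0.48, camera adjusted p = 9.99e-10), or 21 and 1 adjusted over the list alone. The cartilage genes col11a2 and acana (aggrecan) had log2 changes of -1.39 and -1.60 in the authors' deposited table. Of 13 mitochondrially encoded genes, 9 fell and 0 rose (median -0.76, camera adjusted p = 2.24e-06), or 11 and 0 adjusted over the list alone. In the DNA damage response list 15 of 34 rose and 0 fell (median 0.55, camera adjusted p = 5.94e-06), or 16 and 0 adjusted over the list alone, and cdkn1a rose by 1.63 in the authors' deposited table, whereas mdm2 had a log2 change of 0.60 and did not pass (adjusted p = 0.247). The separate DNA repair list had 2 of 45 higher and 2 lower, and did not pass (median 0.04, camera adjusted p = 0.689). Erythrocyte and heme genes rose in 12 of 30 cases and fell in 0 (median 0.50, camera adjusted p = 2.87e-07), or 13 and 0 adjusted over the list alone. These list calls, apart from the leukocyte markers, held at an inter-gene correlation of 0.1. The photoreceptor list had 11 of 35 lower and 0 higher (median -0.42, camera adjusted p = 1.88e-04), 14 lower adjusted over the list alone, but adjusted p = 0.0818 at 0.1. The neuron and glia list had 10 of 49 lower and 2 higher (median -0.44, camera adjusted p = 2.19e-04), 21 and 4 adjusted over the list alone, and adjusted p = 0.118 at 0.1.

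The cyclooxygenase genes, whose products diclofenac inhibits, were measured as fixed before the data were examined. The inducible forms ptgs2a and ptgs2b rose by 1.32 and 2.85 in the authors' deposited table (adjusted p = 6.54e-05 and 9.43e-11). The constitutive form ptgs1 had a log2 change of 0.44 in the authors' deposited table, and did not pass (adjusted p = 0.0994). The Ah receptor targets had a median of -0.07, with 1 higher and 3 lower of 17 (camera adjusted p = 0.847); adjusted over the list alone 2 were higher and 3 lower. Of these, cyp1a had a log2 change of -0.38 in the authors' deposited table and did not pass (adjusted p = 0.379), while cyp1b1 rose by 1.16 and cyp1c1 fell by 0.72.

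Diclofenac changed 3495 entries, 1843 higher and 1652 lower, of which 1462 changed at least 2-fold.

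**Figure D2:**
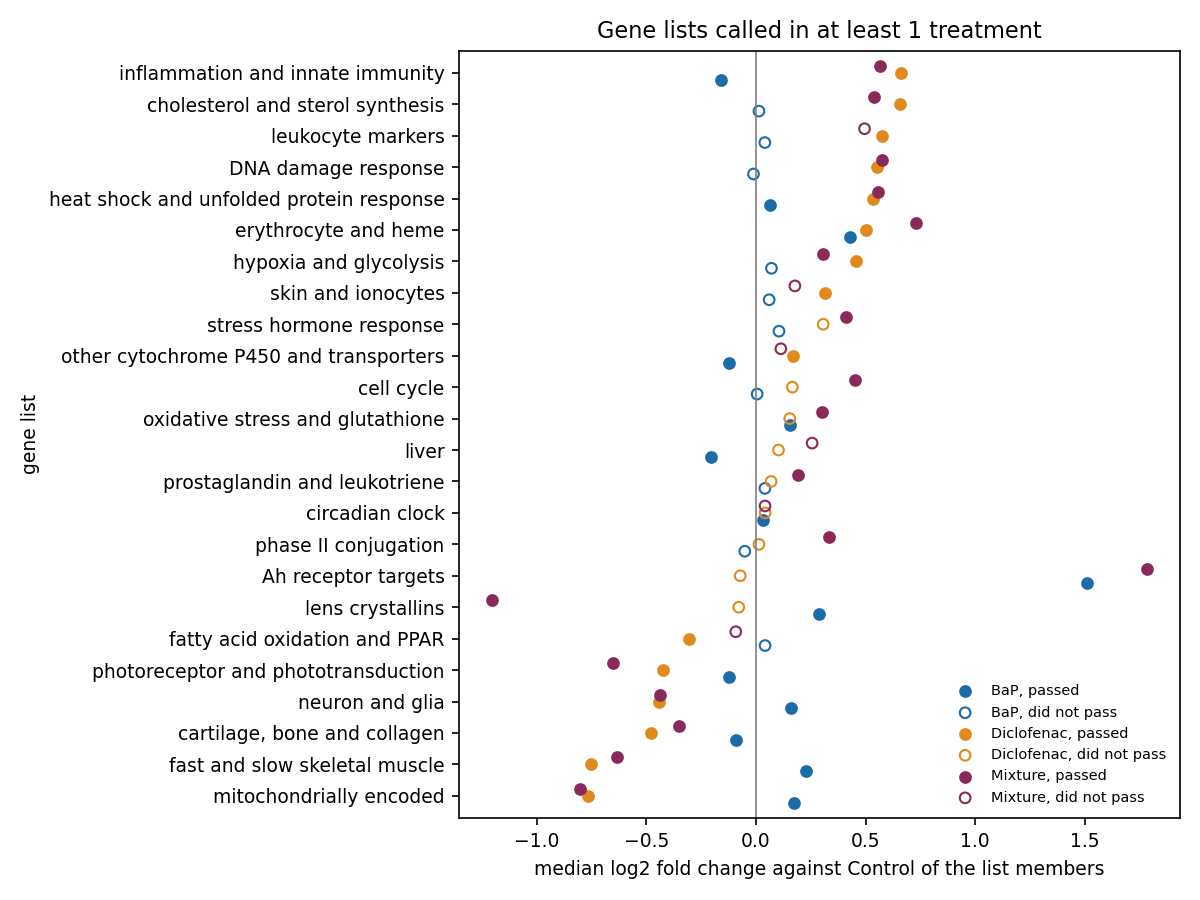
Median log2 fold change against Control of the members of each gene list called in at least 1 treatment, with filled points for lists past an adjusted p of 0.05 (camera, inter-gene correlation 0.01) and open points for the others. The skeletal muscle list lies at -0.75 with diclofenac and at -0.63 with the mixture, and the Ah receptor targets at 1.51 with BaP and at 1.78 with the mixture.

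The third comparison asked what the mixture changed. Ah receptor targets and stress and sterol synthesis genes rose, and skeletal muscle, lens, photoreceptor and neuronal genes fell. In the authors' deposited table cyp1a rose by 7.28, cyp1b1 by 4.27 and cyp1c1 by 3.91 (adjusted p = 9.30e-110, 1.14e-85 and 1.63e-56, likelihood ratio test). The stress genes fosl1a, hspb11 and atf3 rose by 5.43, 5.41 and 4.63 in the authors' deposited table. The cyclooxygenase genes ptgs1 and ptgs2b rose by 0.73 and 3.13 in the authors' deposited table (adjusted p = 0.00177 and 8.87e-13), and ptgs2a rose 2.31-fold (adjusted p = 3.90e-04). The muscle genes ampd1 and tnni2b.2 had log2 changes of -5.08 and -2.85 in the authors' deposited table, whereas tcap rose by 5.18.

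Of the Ah receptor targets 14 of 17 rose and 0 fell (median 1.78, camera adjusted p = 6.78e-41), and the counts adjusted over the list alone were also 14 and 0. Of 46 measured lens genes, most of them crystallins (the main proteins of the lens), 26 fell and 0 rose (median -1.20, camera adjusted p = 1.37e-14), and adjusted over the list alone 34 fell. With the members taken as fully correlated, that median over its implied SE gave p = 0.00181 (two-sided normal test, unadjusted). The crystallin genes crygm2d16 and crygm2d15 had log2 changes of -2.01 and -2.14 in the authors' deposited table, and since these are near-identical copies the split of reads among them is uncertain. Photoreceptor genes fell in 12 of 35 cases and rose in 0 (median -0.65, camera adjusted p = 2.46e-07), or 15 and 0 adjusted over the list alone. Neuron and glia genes fell in 17 of 49 cases and rose in 1 (median -0.44, camera adjusted p = 2.87e-06), or 23 and 1 adjusted over the list alone. Skeletal muscle genes fell in 39 of 69 cases and rose in 5 (median -0.63, camera adjusted p = 7.43e-17), or 47 and 8 adjusted over the list alone. Heat shock and unfolded protein genes rose in 25 of 50 cases and fell in 0 (median 0.56, camera adjusted p = 1.84e-35), or 28 and 2 adjusted over the list alone. Cholesterol synthesis genes rose in 12 of 26 cases and fell in 0 (median 0.54, camera adjusted p = 5.38e-06), or 14 and 0 adjusted over the list alone. Inflammation and innate immunity genes rose in 15 of 46 cases and fell in 1 (median 0.57, camera adjusted p = 2.72e-11), or 19 and 2 adjusted over the list alone. In the DNA damage response list 17 of 34 rose and 0 fell (median 0.58, camera adjusted p = 1.81e-09), or 20 and 1 adjusted over the list alone. In the authors' deposited table cdkn1a rose by 2.23, and mdm2 had a log2 change of 0.56 and did not pass (adjusted p = 0.295). The DNA repair list had 3 of 45 higher and 0 lower, and did not pass (median 0.22, camera adjusted p = 0.138, and 0.0276 by ranks). Cartilage, bone and collagen genes fell in 16 of 38 cases and rose in 2 (median -0.35, camera adjusted p = 2.46e-07), or 16 and 3 adjusted over the list alone. Mitochondrially encoded genes fell in 9 of 13 cases and rose in 0 (median -0.80, camera adjusted p = 1.01e-06), and the counts adjusted over the list alone were also 9 and 0. Erythrocyte and heme genes rose in 19 of 30 cases (median 0.73, camera adjusted p = 3.07e-12), or 24 adjusted over the list alone, with the embryonic globin gene hbbe3 at 2.52 in the authors' deposited table. Oxidative stress and glutathione genes rose in 13 of 36 cases and fell in 1 (median 0.30, camera adjusted p = 1.20e-05), or 15 and 1 adjusted over the list alone. Cell cycle genes rose in 6 of 47 cases (median 0.45, camera adjusted p = 3.70e-06), or 3 adjusted over the list alone. All of these list calls held at an inter-gene correlation of 0.1. Phase II conjugation genes rose in 14 of 45 cases and fell in 1 (median 0.33, camera adjusted p = 8.31e-04), or 15 and 1 adjusted over the list alone, with adjusted p = 0.143 at 0.1.

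The mixture changed 3199 entries, 1756 higher and 1443 lower, of which 1324 changed at least 2-fold. Of the 3495 entries called with diclofenac, 62.8% were also called in the same direction with the mixture (exact 95% binomial interval 61.1 to 64.4, which treats entries as independent). Entries called higher in both numbered 1237, against 150 for independent lists of these sizes, and entries lower in both 957, against 110. The fold changes of the 2 treatments correlated across entries with r = 0.771, where unchanged groups sharing the control libraries gave 0.4995 in 100 simulated draws, and genes are not independent replicates. The covariance was 0.371 against 0.0646 simulated. The covariance thus exceeded the simulated value by 0.307, and the simulated groups had a mean of 0 entries called in both. The draws gave each entry independent noise, so they do not cover controls that deviate alike across many genes. BaP against the same controls gave only 32 calls, and the mixture against BaP, where Control cancels, gave 3556. These 2 counts argue against shared controls alone as the source of the overlap. Shared controls may still add to it among changed entries, which the simulation did not hold. For BaP and the mixture r was 0.295, with a covariance of 0.0767 against 0.0646 simulated. The simulated r holds for unchanged groups, and the mixture changed 3199 entries, so that r is no reference for this pair. Of the 25 entries higher with BaP, 22 were higher again with the mixture. Of the 7 lower with BaP 1 was lower again, and 1 entry was called in opposite directions.

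**Figure D3:**
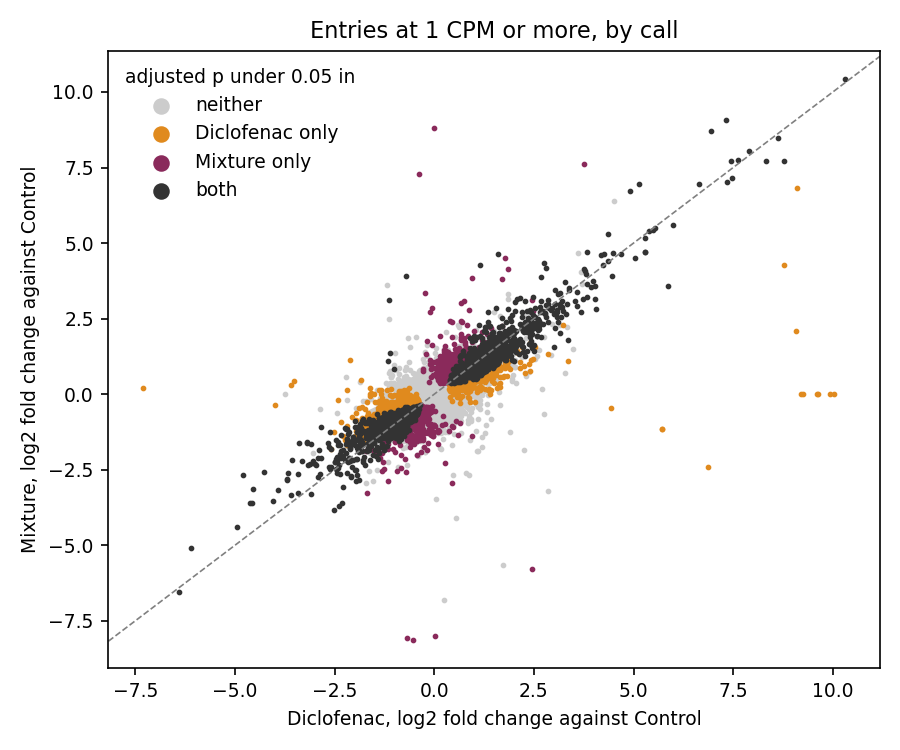
Log2 fold change against Control of the 21622 entries, with diclofenac on the x axis and the mixture on the y axis, coloured by which comparison called them; the dashed line marks equal change. Of the entries called with diclofenac, 98.6% had a change of the same sign with the mixture, and 5 entries were called in opposite directions.

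The fourth comparison, of the mixture with BaP alone, asked what adding diclofenac changed. Like the comparisons that follow, it assumes that the mixture held each compound at the dose used alone, and no dose is given here. Stress and inflammation genes were higher and muscle, lens, neuronal and mitochondrially encoded genes lower. By an approximate Wald test on the implied variances, fosl1a differed by 5.13 ± 0.25 (log2, implied SE; adjusted p = 3.53e-92) and hspb11 by 4.90 ± 0.25 (adjusted p = 1.79e-78). The muscle gene igfn1.3 differed by -6.77 ± 0.25 (adjusted p = 1.30e-154). The cyclooxygenase genes ptgs1, ptgs2a and ptgs2b were higher by 0.79 ± 0.19, 1.18 ± 0.28 and 2.51 ± 0.41 (adjusted p = 7.03e-04, 5.37e-04 and 6.35e-08). Among Ah receptor targets cyp1c1 was higher by 0.98 ± 0.24 (adjusted p = 8.07e-04) and foxq1a by 0.88 ± 0.26 (adjusted p = 0.00789), whereas the difference in cyp1a, 0.48 ± 0.32, did not pass (adjusted p = 0.346).

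Ah receptor targets were higher in 4 of 17 cases (median 0.46, camera adjusted p = 0.0396), or 5 adjusted over the list alone, with adjusted p = 0.267 at an inter-gene correlation of 0.1. Lens genes were lower in 37 of 46 cases (median -1.53, camera adjusted p = 1.07e-21), or 39 adjusted over the list alone. Photoreceptor genes were lower in 11 of 35 cases and higher in 0 (median -0.45, camera adjusted p = 8.66e-05, and 0.0615 at 0.1), with the same counts adjusted over the list alone. Neuron and glia genes were lower in 27 of 49 cases and higher in 1 (median -0.64, camera adjusted p = 1.63e-09), or 32 and 3 adjusted over the list alone. Skeletal muscle genes were lower in 45 of 69 cases and higher in 2 (median -0.85, camera adjusted p = 1.64e-27), or 47 and 3 adjusted over the list alone. Heat shock and unfolded protein genes were higher in 26 of 50 cases and lower in 0 (median 0.53, camera adjusted p = 2.72e-28), or 27 and 2 adjusted over the list alone. Inflammation and innate immunity genes were higher in 21 of 46 cases and lower in 2 (median 0.78, camera adjusted p = 3.93e-16), or 23 and 2 adjusted over the list alone. Mitochondrially encoded genes were lower in 11 of 13 cases and higher in 0 (median -0.96, camera adjusted p = 1.63e-09), or 12 and 0 adjusted over the list alone. Liver genes were higher in 16 of 42 cases (median 0.48, camera adjusted p = 3.66e-05), with 20 higher and 1 lower adjusted over the list alone, and adjusted p = 0.0615 at 0.1. In total 3556 entries differed, 1801 higher and 1755 lower.

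The fifth comparison, of the mixture with diclofenac alone, asked what adding BaP changed. Ah receptor targets were higher and lens genes lower. The difference was 7.66 ± 0.32 for cyp1a, 4.63 ± 0.24 for cyp1c1 and 4.28 ± 0.26 for foxq1a (log2, implied SE; adjusted p = 4.31e-121, 5.45e-79 and 9.19e-57). Among conjugation genes ugt1b1, a glucuronosyltransferase, was higher by 1.82 ± 0.26 (adjusted p = 5.69e-09). The prostaglandin transporter gene slco2a1 was higher by 2.31 ± 0.41 (adjusted p = 2.24e-05). The lens filament genes BFSP1 and bfsp2 differed by -1.95 ± 0.28 and -1.57 ± 0.34 (adjusted p = 5.69e-09 and 0.00233), and hsf4, a lens transcription factor gene, by -1.67 ± 0.35 (adjusted p = 0.00146).

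Of the Ah receptor targets 12 of 17 were higher and 0 lower (median 1.82, camera adjusted p = 1.81e-137), or 13 and 0 adjusted over the list alone. Lens genes had a median of -1.12, with 3 of 46 lower over all entries and 38 lower adjusted over the list alone (camera adjusted p = 2.83e-43). Phase II conjugation genes had a median of 0.18, with 5 of 45 higher and 0 lower, or 7 and 0 adjusted over the list alone (camera adjusted p = 5.30e-07, and 0.0420 at 0.1). Cell cycle genes had a median of 0.30 and 45 of 47 values above 0, with 0 called, also adjusted over the list alone (camera adjusted p = 8.21e-08, and 0.0337 at 0.1). The correlation among lens genes could not be estimated without values per library, so their camera p rests on the preset. Photoreceptor genes had a median of -0.15, with 1 of 35 lower, or 2 adjusted over the list alone (camera adjusted p = 0.0535). Skeletal muscle genes had a median of 0.20, with 2 higher and 0 lower of 69, or 4 and 1 adjusted over the list alone (camera adjusted p = 1.71e-05, and 0.131 at 0.1); the actin gene acta1b was higher by 1.09 ± 0.21 (adjusted p = 2.54e-04). Altogether 79 entries differed, 48 higher and 31 lower, and 122 with the median of the implied variances in place of the largest.

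**Figure D4:**
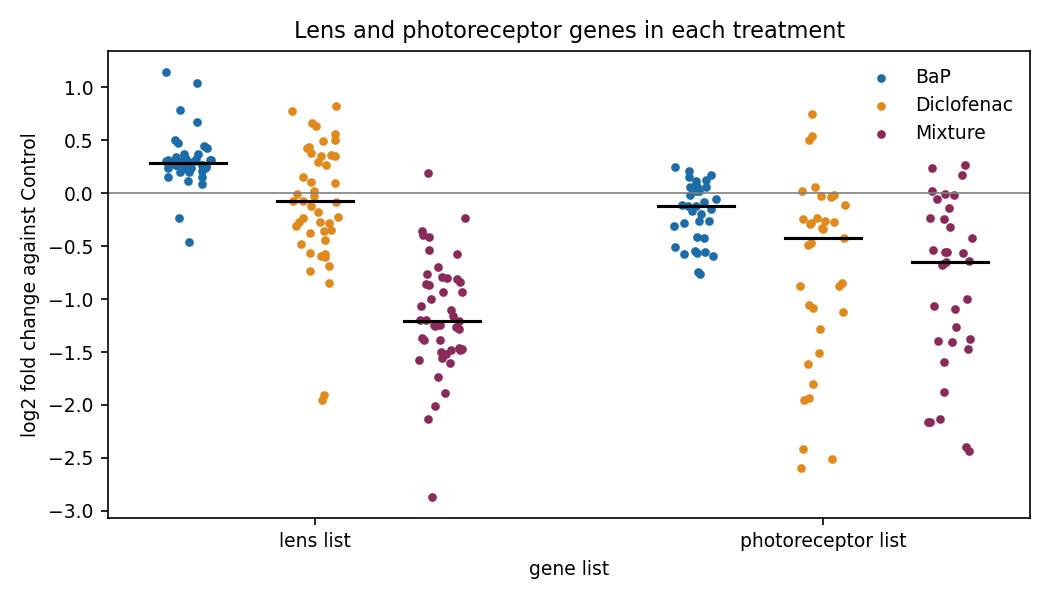
Log2 fold change against Control of each measured lens gene and photoreceptor gene after BaP, diclofenac or the mixture, with black lines at the medians. The lens medians lie at 0.29, -0.08 and -1.20, and the photoreceptor medians at -0.12, -0.42 and -0.65, in that order.

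The last comparison asked whether the mixture departed from the sum of the log2 changes of its parts, the question of interaction in the study's title. It rests on the same assumption of equal doses. A departure from that sum passed the test for 10 of 21622 entries, 3 above it and 7 below. The number of calls was 29 with the median of the implied variances in place of the largest, and 5 with 1 entry per symbol or with Benjamini-Yekutieli adjustment. At an unadjusted p under 0.05 there were 979, against 1081 that uniform p-values would give. That is 4.53% of entries, beside 4.47% of unchanged genes by the same test on simulated counts. The Ah receptor targets foxq1a and cyp1c1 exceeded the sum by 2.02 ± 0.37 and 1.70 ± 0.34 (log2, implied SE; adjusted p = 2.86e-04 and 0.00245). The lens genes BFSP1 and crygm2d18 fell short of it, at -2.29 ± 0.40 and -1.95 ± 0.46 (adjusted p = 7.78e-05 and 0.0401). For foxq1a and cyp1c1 the departures were larger than their differences from BaP alone, given above. Both had negative log2 changes with diclofenac alone, cyp1c1 at -0.72, and these changes enter the departure.

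Lens genes had a median interaction of -1.43, with 1 of 46 lower over all entries and 39 lower adjusted over the list alone (camera adjusted p = 1.77e-49, and 3.36e-13 at a correlation of 0.1). With the members taken as fully correlated, that median over its implied SE of 0.545 gave p = 0.00873 (two-sided normal test, unadjusted). The Ah receptor targets had a median of 0.52, with 2 of 17 higher, or 3 adjusted over the list alone (camera adjusted p = 4.53e-04, and 0.0704 at 0.1). Liver genes had a median of 0.40 with 0 of 42 called either way, also adjusted over the list alone (camera adjusted p = 1.34e-07, and 0.0389 at 0.1). The liver call rests on the preset correlations, since its members were not tested as fully correlated. The cyclooxygenase genes ptgs1, ptgs2a and ptgs2b departed by 0.35 ± 0.27, -0.14 ± 0.40 and -0.34 ± 0.58 (adjusted p = 0.999 for each). On simulated counts the test recovered 26% of interactions of 1 log2 unit and 68% of those of 2, so smaller departures were mostly not detectable.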

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

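The tests of explanations, and the inter-gene correlation of 0.1, were chosen after the result was seen, whereas the interaction was a question fixed before, tested by an approximation chosen later. How often other splits of the 12 libraries would give as many calls was not counted, since that needs values per library, and so chance groupings stay untested for every count.

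The effect of BaP with diclofenac present differed from its effect alone, by the interaction test, for 10 entries. Equal doses in the mixture and in the single treatments were assumed. Above the sum of the single changes were rpe (9.19, log2), foxq1a (2.02) and cyp1c1 (1.70). Below it were med6 (-15.05), plod3 (-2.53), BFSP1 (-2.29), aifm5 (-2.28), crygm2d18 (-1.95), stau2 (-1.03) and prx (-0.97). By camera at an inter-gene correlation of 0.01, 13 lists passed for the interaction, but only lens and liver did at 0.1 (adjusted p = 3.36e-13 and 0.0389), the other 11 giving 0.0704 to 0.440. Of their members, 2 Ah receptor targets and 1 gene of the lens list were called, and 0 in the other lists. Median interactions were 0.52 for Ah receptor targets, 0.40 for liver, 0.26 for cell cycle, 0.26 for fatty acid oxidation, 0.25 for phase II conjugation, 0.22 for cartilage and 0.14 for heat shock genes. They were -1.43 for lens, -0.32 for leukocyte markers, -0.26 for erythrocyte and heme, -0.20 for hypoxia and glycolysis, -0.20 for neuron and glia and -0.12 for skin and ionocyte genes.

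Lens genes were lower in the mixture than with diclofenac alone, with a median of -1.12 and 45 of 46 members lower. Less eye tissue in those libraries is argued against by the photoreceptor genes, whose median difference was -0.15 with a lower quartile of -0.32. Reads shared among near-identical gamma M crystallins are argued against by the 22 lens genes outside that family, whose median was -1.13 with an upper quartile of -1.08. A few libraries holding little lens tissue may account for the pattern: the implied variance of lens genes lay above 100% of 10000 random lists matched on abundance, although any source of variable lens transcripts would give that too. With the members taken as fully correlated and an implied SE of 0.386, the median of -1.12 gave p = 0.00360 (two-sided normal test, unadjusted). That SE rests on the authors' model of the spread, and was not measured among the mixture libraries. The p therefore cannot weigh against a few libraries holding little lens tissue. An effect of the mixture on the lens stays open as a hypothesis beside a few libraries holding little lens tissue, and values per library would be needed to separate them.

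Some scarce entries appeared to switch on or off, with a log2 change beyond 5 at an average under 4 CPM. There were 30 such entries with diclofenac or the mixture, 10 of them also beyond that limit with BaP. Switching of all entries of a symbol is argued against for the 25 that share a symbol with another entry. The most abundant other entry moved by a median of only -0.0815 in the same direction, with an upper quartile of 0.17. Reads moved between entries of the same symbol may account for them: 83.3% shared their symbol with another entry against 41.4% of the other scarce entries (Fisher's exact test, two-sided, p = 5.26e-06). The table has 30628 gene identifiers for 26240 symbols, so the other entry can belong to another gene identifier. Both barhl2 and znf143b hold more than a single such entry, so the entries are not all independent. The large change of med6 is of this kind, no biological explanation was tested, and 5 entries without a partner stay open.

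Ah receptor targets were higher in the mixture than with BaP alone, with a median difference of 0.46 and 14 of 17 members higher. Singly, foxq1a and cyp1c1 departed from additive log2 changes by the interaction test above. For the 17 targets as a list additive changes cannot be told apart from a departure, since their median interaction was 0.52 but the list test at a correlation of 0.1 gave adjusted p = 0.0704. The authors' scaling moves all entries of a library alike, so it cannot by itself lift the targets above the other entries. The median difference over all entries was 0.0146. Whether the targets stood above the other entries was uncertain (camera, adjusted p = 0.0396 at a correlation of 0.01 and 0.267 at 0.1). A joint effect of both compounds stays open beside additive changes as a hypothesis, and it assumes equal doses.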

How the results depend on the processing

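The alternatives other than no abundance filter, 5 CPM and 2-fold were chosen after seeing the data. No paired analysis was possible because the table analysed here holds comparisons and no values per library; for that reason other normalizations, tools, pseudocounts, samples in the fit, left-out replicates, estimated correlations and rotation tests were not run either. Requiring 2-fold left 1462 entries for diclofenac, 1324 for the mixture and 1462 for the mixture against BaP, and the limit of 1.5 left 666, 546 and 566, with 37 for the mixture against diclofenac, since each removes smaller changes. Benjamini-Yekutieli adjustment, stricter by construction, left 21 for BaP, 1792 for diclofenac, 1551 for the mixture, 1786 for the mixture against BaP, 41 against diclofenac and 5 for the interaction. The median variance gave 122 for the mixture against diclofenac and 29 for the interaction, and 1 entry per symbol gave 5 for the interaction; the cause was not tested. An inter-gene correlation of 0.05 left 7 lists of 14 for BaP, 9 of 14 for the mixture against diclofenac and 6 of 13 for the interaction. At 0.1 there were 4 for BaP, 8 of 15 for diclofenac, 9 of 17 for the mixture against BaP, 4 against diclofenac and 2 for the interaction. The 62.8% of diclofenac calls shared with the mixture moved to 59.0% without the filter, 65.2% at 5 CPM and 64.5% with 1 entry per symbol; the cause was not tested. Named entries were checked under 6 settings (both filters, median-centred changes, Benjamini-Yekutieli, median variance, 1 entry per symbol) but not under the fold limits, where smaller changes fail by construction: 1319 checks of called ones kept the call in 1297 cases and lost it in 22, and 740 checks of those not called gained one in 6. Lists were checked under 7 (both filters, median-centred changes, both correlations, ranks, protein-coding entries alone): for called ones 637 checks kept the call in 545 cases and lost it in 92, and 695 checks of lists not called gained one in 26. The counts hold 0 reversals. Depth per library is unknown here, so what it limits could not be assessed.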

Other observations

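The prolactin gene prl fell with BaP but rose with diclofenac and with the mixture, at -1.36, 2.45 and 1.52 in the authors' deposited table. The ammonia transporter gene rhcgb rose by 2.64 with BaP and fell with diclofenac, at -2.11 in the authors' deposited table. The vitamin D hydroxylase gene cyp24a1 rose by 4.04 with diclofenac and by 3.14 with the mixture in the authors' deposited table. Of these genes, rhcgb and cyp24a1 were chosen after their values were seen.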
